A study of Mus musculus with 3 samples.

How the data were processed

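Single-cell RNA sequencing libraries were prepared from CD3-sorted cells of MC38 tumours, a mouse colon carcinoma line grown in mice. Per the labels, tumours were taken on day 15 after 5 days of treatment, digested, stained for CD3 and sorted by flow cytometry, and the libraries were made with a 10x Genomics Chromium 3′ kit. There were 3 libraries, labelled PBS, mix and homo, with 1 library per group. The labels do not say what was given under mix or homo, so these groups are called by their labels throughout. The labels also do not say how many animals were pooled in a library.

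The values analysed were raw UMI counts per gene and cell barcode as deposited, made with Cell Ranger 7.1.0 per the file headers. The submitters' processing notes name Cell Ranger 2.1.1, Seurat 4.1.0 and the genome build mm39, so the version differs between the notes and the headers. Each library held counts for 32285 genes, and every barcode held at least 500 UMIs, so barcodes had already been limited to called cells. Sequence coordinates of mm39 were not used here, and genes are given by the symbols in the files. Symbols stand for whole genes, and reads shared between near-identical paralogs, such as the neighbouring granzyme genes Gzmc to Gzmg or Hspa1a and Hspa1b, cannot be told apart from these counts.

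From these counts, barcodes with at least 500 genes, at least 1000 UMIs and under 10% mitochondrial UMIs were kept. Scrublet, run per library in scanpy 1.11.5, found 798 doublets in PBS and 0 in mix and homo with its own threshold, so that threshold was not used. Instead the barcodes with the highest scores were removed in each library, at 0.8% for every 1000 kept barcodes. This left 9214 cells in PBS, 7588 in mix and 7303 in homo. Counts were scaled per cell and log-transformed, and 2000 variable genes were chosen without T cell receptor, immunoglobulin, mitochondrial, ribosomal protein, haemoglobin, cell cycle, stress and sex-linked genes. Cells of the 3 libraries were clustered together on 30 principal components with 15 neighbours and Leiden clustering at resolution 1.0 (leidenalg 0.10.2), first all cells and then the T-like cells alone. No correction between libraries was made in the main setting. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3 were used.

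Cell type markers, 14 gene lists, the rule for named genes, the comparisons and most alternative settings were chosen before the data were examined. The shares of cells with lineage genes that a cluster needed for its name were set after the data were seen. In the first clustering, of all cells, a cluster was named after a non-T cell type with at least 3 leading markers of that type. Otherwise it was T-like where CD3 genes were found in at least 50% of cells. NK markers were not weighed in this step, so no cluster could be named NK. Among T-like cells, a CD8-like cluster needed Cd8a or Cd8b1 in 60% of cells and Cd8b1 in 50%, with Cd4 or Foxp3 in at most 10% each. A regulatory-like cluster needed Foxp3 in 40% and CD8 genes in at most 35%. A cluster also needed at least 3 detected markers, and stayed unnamed where markers of another T cell class outnumbered its own among its 10 leading genes or where its median UMI count was far below that of its libraries. Among these leading genes, only the T cell classes were weighed for clusters of T-like cells. Plac8 was among the 10 leading genes of CD8-like cluster 1, Spp1 of cluster 8 and Itgax of cluster 13. These genes stand on the myeloid or dendritic marker lists. Because these names were rebuilt from markers, class shares given elsewhere for this study may rest on other names.

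With 1 library per group there was no test, and no p-value or standard error is given. UMIs were summed over the cells of a class in each library and scaled by the summed UMIs of the class to CPM. Ratios of CPM carry an exact conditional binomial 95% interval for 2 Poisson counts, and shares of cells carry an exact Clopper-Pearson 95% interval. All intervals cover counting error only, not differences between animals, digests or library preparations. A gene entered a comparison with a CPM of at least 50 in either library, and genes at least 2-fold apart were counted.

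The named genes are the 10 highest and the 10 lowest in CD8-like cells, and the 5 highest and 5 lowest in other classes, ranked by the end of the interval nearest 0. T cell receptor, immunoglobulin, mitochondrial, ribosomal protein, haemoglobin and sex-linked genes and unnamed gene models were left out of this ranking. Lag3, Il2ra, Il2rb, Il2rg, Pdcd1, Havcr2, Tcf7, Gzmb, Ifng, Mki67, Foxp3, Cd8a and Cd4 were always named, with up to 4 members of each gene list. No cluster met the limits for CD4 conventional-like cells, so the rule was run on all T-like cells in their place.

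The 14 lists covered inhibitory receptors and exhaustion-associated genes, cytotoxic effector genes, naive, memory and stem-like genes, proliferation genes, IL-2 receptor and STAT5 target genes, regulatory T cell genes, interferon-stimulated genes, helper cytokines and lineage factors, migration and residency genes, T cell receptor-induced genes, glycolysis genes, respiratory chain genes, apoptosis regulators, and immediate early and heat shock genes. Of the listed symbols, 7 were not matched in the files. Some genes stand on more than 1 list; the regulatory T cell list and the T cell receptor-induced list share 4 genes. A list's median log2 ratio was taken over members with at least 20 UMIs in the 2 libraries and set against 10000 random lists of the same size matched on mean expression in 20 bins. A list stood apart where its median lay among the lowest or highest 2.5% of these, which describes these libraries only. Random members were drawn independently of each other, while members of a list can vary together. The percentiles can therefore be too extreme, and a list with a small median can lie beyond all random lists. Members at least 1.5-fold apart were counted as higher or lower.

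To compare shares of cells with a UMI of a gene, each cell was thinned to 2000 UMIs and shallower cells were left out. The computations were tested on counts simulated from the Poisson model that the intervals assume, which checks the arithmetic and not the model. These had 200 altered genes, on 13489 genes for homo against PBS in CD8-like cells. There the interval held the true ratio for 95.4% of unaltered genes and 88.1% of genes altered 1.5-fold, 100% of genes altered 4-fold were found at least 2-fold apart, and 56.5% of those altered 2-fold. For the same comparison in regulatory-like cells, with 9961 genes, these shares were 96.6%, 100%, 100% and 53.2%.

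The alternatives tried were no doublet removal, a stricter cell filter of 1000 genes, 2000 UMIs and 5% mitochondrial UMIs, resolutions of 0.5 and 2.0, components centred per library, a gate on UMIs per cell in place of clusters, median-of-ratios scaling, scaling without mitochondrial, ribosomal and T cell receptor genes, a mean of per-cell CPM, thinned cells, other CPM and UMI minimums, and other depths and minimums for shares of cells. A looser naming rule without doublet removal, CD8-like cells without cluster 6, and regulatory-like cells with cluster 15 added were chosen after the data were seen.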

Results

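Transcripts were counted in single CD3-sorted cells of MC38 tumours from mice given PBS or 1 of 2 treatments labelled mix and homo. The series title concerns interleukin-2 directed to LAG3, an inhibitory receptor of T cells, and the 3 libraries allow the treated tumours to be set against PBS and against each other. The PBS library held 10351 barcodes and 56427870 UMIs, with a median of 4748 UMIs and 1856 genes per barcode. The mix library held 8461 barcodes and 49179708 UMIs, with medians of 4955 UMIs and 1924 genes. The homo library held 8528 barcodes and 65336646 UMIs, with medians of 6582 UMIs and 2254 genes. Barcodes over the mitochondrial limit made up 4.07% of the homo library, against 0.251% in PBS and 0.307% in mix. With 1 library per group none of the differences below has a replicate check, and intervals cover counting error only.

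T-like cells made up nearly all analysed cells, and regulatory-like cells were a lower share of them in homo. T-like cells were 98.7% of cells in PBS (95% interval 98.4 to 98.9), 98.9% in mix (98.7 to 99.2) and 99.8% in homo (99.7 to 99.9), after a sort on CD3 that would itself set this share. Regulatory-like cells, which carried Foxp3, the transcription factor of regulatory T cells, were 14.8% of T-like cells in PBS (14.1 to 15.6), 17.3% in mix (16.4 to 18.2) and 2.61% in homo (2.25 to 3.0). The share in PBS was 5.69-fold that in homo, and the share in mix was 6.63-fold that in homo. CD8-like cells were 75.7% of T-like cells in PBS (74.8 to 76.6), 73.0% in mix (72.0 to 74.0) and 82.7% in homo (81.8 to 83.5).

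Few cells were named as other types, and NK cells could not be named by the rule used. A cluster of 560 cells led by Klra7, Klra6 and Klra1, with CD3 genes in 95.9% of cells, was counted as T-like. Macrophage-like cells numbered 66 in PBS, 31 in mix and 8 in homo, and dendritic-like cells 54, 49 and 7. No cluster was CD4 conventional-like in the main setting, while at resolution 2.0 such clusters held 1.65% of T-like cells in PBS, 1.90% in mix and 1.43% in homo. With the UMI gate per cell, cells with Cd4 and without Foxp3 or CD8 genes were 3.47% in PBS, 4.12% in mix and 0.967% in homo. Unnamed clusters held 9.47% of T-like cells in PBS, 9.68% in mix and 14.7% in homo, and the limits that left them unnamed were set after the data were seen. Counting one of them, cluster 15, whose cells held CD8 and regulatory genes together, as regulatory-like lowered the PBS to homo fold to 2.90. Without doublet removal the CD8-like share of homo was 39.8%, because its main cluster then lost its name.

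**Figure D1:**
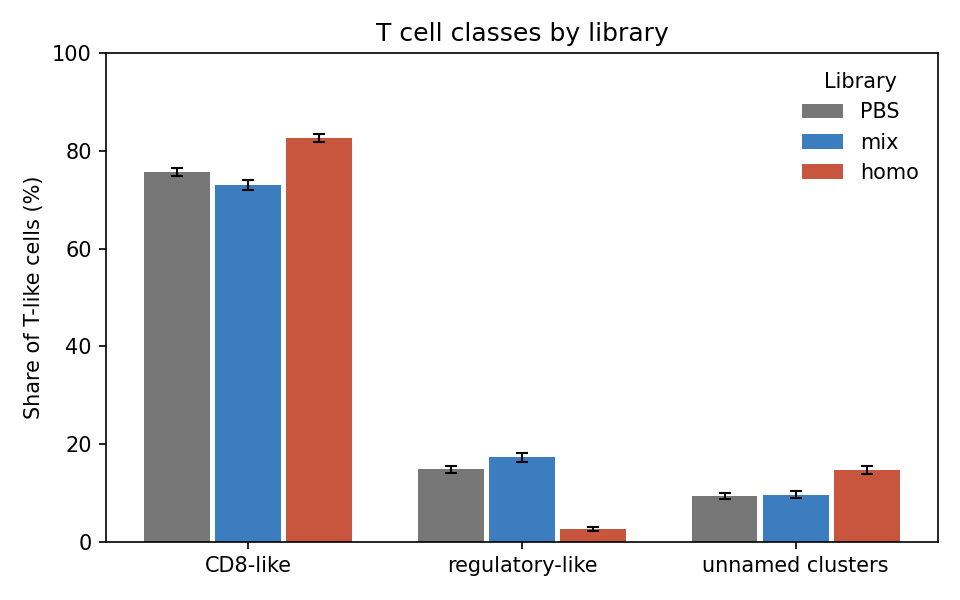
Share of T-like cells (%, from 0) that were CD8-like, regulatory-like or in unnamed clusters in the PBS, mix and homo libraries, with exact 95% intervals for counting error as error bars. The regulatory-like bar of homo, at 2.61%, lies below those of PBS at 14.8% and mix at 17.3%.

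CD8-like cells were compared first between homo and PBS, on summed UMIs of each gene scaled by all UMIs of the class (CPM). Gzma, a granule protease of cytotoxic cells, was 2.98-fold higher in homo (926 against 311 CPM, log2 ratio 1.58, 95% interval 1.55 to 1.61). The interferon-induced membrane proteins Ifitm1 and Ifitm2 were higher by log2 ratios of 1.14 and 0.99, the metallothionein Mt2 by 1.51, and the collagen-binding integrin subunit Itga1 by 1.03. Lower in homo were Klf2, a transcription factor of T cell quiescence and recirculation, with a log2 ratio of -2.28, the granzyme inhibitor family member Serpinb9b with -2.92, and Gzmg with -2.27. Gzmb, the main granule protease of effector CD8 T cells, was at 1771 CPM in homo and 3825 CPM in PBS (log2 ratio -1.11, -1.12 to -1.10).

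Among 3009 genes compared, 21 were at least 2-fold higher in homo and 46 at least 2-fold lower. Leaving out T cell receptor, mitochondrial and ribosomal genes and unnamed models, these were 9 and 41 genes. Others of the highest were Mxd4, a partner of MAX that opposes MYC, at 1.32, Zc3h7a at 1.20, the mitotic cyclin Ccnb2 at 1.16, the surface protein Cd7 at 1.06 and the aspartic protease Napsa at 1.04. Others of the lowest were the heat shock genes Hspa1b at -1.95 and Hspa1a at -1.69, the kinase phosphatase Dusp1 at -1.78, the transcription factor Cebpb at -1.79, Serpina3g at -1.66, Csrnp1 at -1.66 and the inhibitory receptor Lilrb4a at -1.66. Of the genes named in advance, Lag3 had a log2 ratio of -0.23, Havcr2 (TIM-3) -0.22 and Pdcd1 (PD-1) 0.42. The IL-2 receptor subunits Il2ra, Il2rb and Il2rg had ratios of -0.15, 0.16 and -0.37. The cytokine Ifng was at -0.76, the proliferation marker Mki67 at 0.64, Cd8a at -0.44, Foxp3 at 0.48 (-0.019 with centred components) and Cd4 at -1.39. Tcf7, the transcription factor of stem-like T cells, was at -0.51.

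Proliferation genes were higher in homo over PBS, and several other lists were lower. Of 30 proliferation genes, 8 were at least 1.5-fold higher in homo, 1 was lower and 21 lay between, with Ccnb2 at 1.16, Ube2c at 0.99, Hmgb2 at 0.73 and Birc5 at 0.68; the median was 0.37, above all random lists. Of 27 IL-2 receptor and STAT5 target genes, 1 was higher, 15 were lower and 11 lay between. Among them Socs3 was at -2.00, the survival gene Bcl2 at -1.33 and the cytokine signalling inhibitor Cish at -1.24, and the median of -0.64 lay below all random lists. Of 24 cytotoxic effector genes, 1 was higher, 9 were lower and 14 lay between, with Gzma at 1.58 and the pore-forming Prf1 at -1.36; the median was -0.41, below all random lists. Of 20 naive, memory and stem-like genes, 0 were higher, 6 were lower and 14 lay between, with Klf2 at -2.28, Id3 at -2.32 and the lymph node homing receptor Ccr7 at -1.52; the median of -0.31 lay at percentile 0.030. It no longer stood apart in 5 alternative settings. Without doublet removal it was -0.0074 when the main cluster of homo lost its name, and -0.18 with the looser naming rule. Of 19 inhibitory receptor and exhaustion-associated genes, 3 were higher, 3 lower and 13 between, with Cd160 at 0.93, Cd200r1 at 1.0, Bhlhe40 at -0.94 and Rgs16 at -0.80, and the median of -0.14 did not stand apart at percentile 9.48. It stood apart as lower at resolution 2.0 (-0.19).

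Among the other lists, 0 of 27 interferon-stimulated genes were higher and 10 were lower, with Oasl2 at -1.72 and Iigp1 at -1.33 and a median of -0.45. Of 16 glycolysis genes, 0 were higher and 7 were lower, with Eno1 at -1.32, Gapdh at -0.82 and Ldha at -0.75 and a median of -0.53. Of 21 T cell receptor-induced genes, 1 was higher and 8 were lower, with Tnfrsf9 (4-1BB) at -1.48 and Tnfrsf4 (OX40) at -1.33 and a median of -0.40. Of 23 immediate early and heat shock genes, 0 were higher and 11 were lower, with Atf3 at -2.01 and a median of -0.57. The medians of these 4 lists lay below all random lists. Of 22 regulatory T cell genes, 4 were higher and 8 lower, with Ebi3 at 2.53 and Areg at -3.35, and the median of -0.30 lay at percentile 0.050.

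Not standing apart were migration and residency genes, with 1 of 19 higher, 6 lower and a median of 0.0033 (Itga1 at 1.03, Itgae at -1.70), and helper cytokines and lineage factors, with 1 of 9 higher, 4 lower and a median of -0.23 (Bcl6 at 1.49, Il2 at -2.74). The same held for respiratory chain genes, with 25 of 25 between and a median of -0.080 (Cox4i1 at 0.21, Uqcrb at -0.38), and for apoptosis regulators, with a median of -0.16 (Bax at -0.31). Helper cytokines and apoptosis regulators each stood apart as lower in 2 alternative settings, 1 of those for helper cytokines being the class without its main cluster of homo.

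Clusters 1, 6 and 12 held 70.0% of the CD8-like cells of homo and 5.29% of those of PBS, while clusters 2, 3, 4 and 5 held 15.8% and 63.8%, so the ratios compare differently composed classes. Clusters 5 and 7 had Cd4 in 8.13% and 8.36% of cells and CD8 genes in 84.5% and 77.0%. They held 13.9% and 8.24% of the CD8-like cells of PBS, against 2.06% and 3.27% in homo. The Cd4 ratio, and in part the Tcf7 and stem-like values, can reflect how many such cells the class held, which was not tested. The Tcf7 ratio turned positive at resolution 0.5 (0.15) and with the UMI gate (0.24). Without doublet removal it was 0.34 with the main cluster of homo unnamed, but -0.16 with the looser naming rule that kept it, and the Gzma ratio was 0.97 when each cell was weighted equally.

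**Figure D2:**
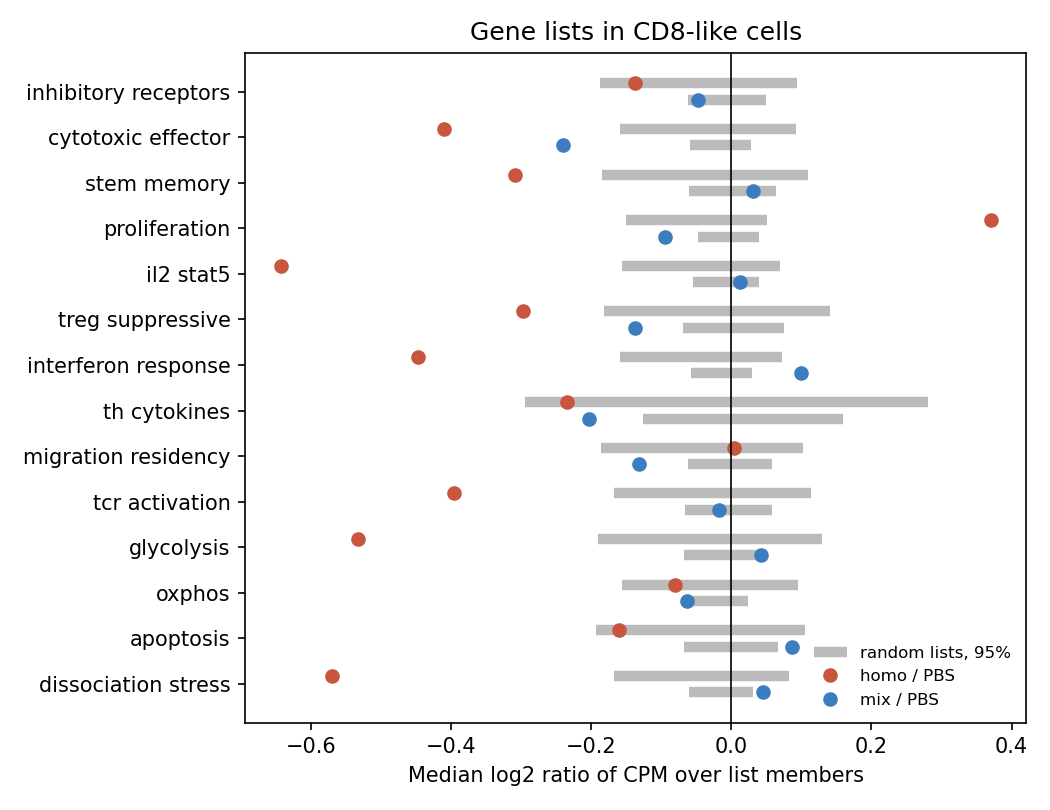
Median log2 ratio of CPM in CD8-like cells for each gene list in homo over PBS and mix over PBS, with grey bars for the middle 95% of random lists. Proliferation genes lie at 0.37 for homo over PBS, and IL-2 receptor and STAT5 target genes at -0.64.

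CD8-like cells of mix and PBS were compared next. Several granzymes were lower in mix, with Gzmg at a log2 ratio of -1.26 (-1.37 to -1.14), Gzma at -1.03, Gzmd at -0.93, Gzmk at -0.77 and Gzme at -0.61, while Gzmb was at 4142 CPM in mix and 3825 CPM in PBS (0.11). The growth factor-like Nrn1 was at -0.80, Serpinb9b at -0.88, the protease inhibitor Serpine2 at -0.76, Sv2c at -0.69 and the integrin subunit Itgb7 at -0.59. Higher in mix were Fah, an enzyme of tyrosine breakdown, at 0.91 (0.85 to 0.97), Zc3h7a at 0.83, Filip1l at 0.83, Erh at 0.80, Ywhaq at 0.69, Jarid2 at 0.63, the receptor Cd244a at 0.55, the glycolytic enzyme Gapdh at 0.55, the interferon-induced Usp18 at 0.45 and Cdk8 at 0.43. Among 2941 genes compared, 3 were at least 2-fold higher and 6 at least 2-fold lower, of which 0 and 2 were outside the T cell receptor, mitochondrial and ribosomal genes and unnamed models.

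Of the genes named in advance, Tcf7 was at 0.35 in mix over PBS, and Cd4 at 0.30. Lag3 was at -0.048, Pdcd1 at -0.016, Havcr2 at -0.15, Il2ra at 0.016, Il2rb at 0.15, Il2rg at -0.0032, Ifng at -0.018, Mki67 at -0.079, Foxp3 at 0.090 and Cd8a at 0.054. Of 24 cytotoxic effector genes, 0 were at least 1.5-fold higher, 6 were lower and 18 lay between, with a median of -0.24, below all random lists. Of 27 interferon-stimulated genes 27 lay between, with Ifi27l2a at 0.29 and Rsad2 at 0.26, and the median of 0.10 lay above all random lists but did not stand apart with the mean of per-cell CPM. Of 30 proliferation genes 30 lay between, with Birc5 at -0.29 and Top2a at -0.22, and the median of -0.094 lay below all random lists. It no longer stood apart with the mean of per-cell CPM (-0.043) or in thinned cells (-0.047).

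Among the remaining lists in this comparison, naive, memory and stem-like genes had a median of 0.031, with 1 of 20 higher (Dapl1 at 0.99), and IL-2 receptor and STAT5 target genes a median of 0.013, with 27 of 27 between (Myc at 0.45, Bcl2 at 0.36). Inhibitory receptor genes had a median of -0.048, with 19 of 19 between (Tox at 0.37), T cell receptor-induced genes a median of -0.017 with 1 of 21 higher, and glycolysis genes a median of 0.042 with 16 of 16 between (Eno1 at 0.40). These 5 lists did not stand apart in the main setting. The naive, memory and stem-like list stood apart in 5 alternative settings. It was higher in 4, among them thinned cells (0.13), and lower at resolution 2.0 (-0.078). Glycolysis genes stood apart as higher in 5, and the IL-2 list at resolution 0.5 (0.039). Regulatory T cell genes (median -0.14, Areg at -1.45), migration and residency genes (-0.13, Ccr2 at -0.67), helper cytokines (-0.20, Il13 at -3.43) and respiratory chain genes (-0.064, Uqcrq at -0.15) lay below the 2.5th percentile. Apoptosis regulators (0.086, Bcl2a1d at 0.25) and immediate early and heat shock genes (0.045, Hsp90aa1 at 0.24) lay above the upper percentile limit. Of these, helper cytokines no longer stood apart in 8 alternative settings, immediate early and heat shock genes in 4, apoptosis regulators in 3 and migration genes in 1. The class was made up differently here too: cluster 8, led by Gzmd and Gzme, held 11.6% of CD8-like cells in PBS and 6.13% in mix, cluster 13 held 6.67% and 0.967%, cluster 6, with Jarid2 and Zc3h7a among its leading genes, 2.48% and 6.06%, and cluster 2, led by interferon-induced genes, 12.8% and 21.9%. The Tcf7 ratio was -0.050 and the Cd4 ratio -0.43 at resolution 2.0.

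Between the treated libraries, homo over mix, Gzma was 926 against 152 CPM in CD8-like cells, a log2 ratio of 2.61 (2.57 to 2.65). The metallothioneins Mt2 and Mt1 were higher in homo by 1.60 and 1.11, Ifitm1 by 1.38, the calmodulin-binding Nrgn by 1.39, the glutathione synthesis subunit Gclm by 1.37, Cd7 by 1.44, the receptor Cd160 by 1.31, the mitotic ubiquitin enzyme Ube2c by 1.15 and Mxd4 by 1.14. Lower in homo were Hspa1b at -2.05, Klf2 at -2.05, Serpinb9b at -2.04, Hspa1a at -1.83, the glycolytic enzyme Eno1 at -1.72, the interferon-induced Oasl2 at -1.77, Bcl2 at -1.69, Lilrb4a at -1.64, Cebpb at -1.61 and Dusp1 at -1.59. Among 3007 genes compared, 21 were at least 2-fold higher in homo and 47 at least 2-fold lower.

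Of the genes named in advance, homo over mix gave Pdcd1 at 0.44, Lag3 at -0.18, Havcr2 at -0.074, Il2ra at -0.16, Il2rb at 0.012, Il2rg at -0.36, Gzmb at -1.23, Ifng at -0.74, Mki67 at 0.72, Tcf7 at -0.86, Foxp3 at 0.39, Cd8a at -0.49 and Cd4 at -1.69. Proliferation genes had a median of 0.50, above all random lists, with 14 of 30 higher and 2 lower (Birc5 at 0.97). Medians below all random lists were -0.55 for IL-2 receptor and STAT5 target genes (2 of 27 higher, 13 lower, Socs3 at -1.99), -0.50 for naive, memory and stem-like genes (9 of 20 lower, Ccr7 at -1.59), -0.58 for interferon-stimulated genes (13 of 27 lower, Irf7 at -0.98), -0.55 for glycolysis genes (7 of 16 lower, Gapdh at -1.37), -0.32 for T cell receptor-induced genes (2 of 21 higher, 8 lower, Tnfrsf9 at -1.49) and -0.58 for immediate early and heat shock genes (11 of 23 lower). Migration and residency genes lay above, at 0.16 (4 of 19 higher, 4 lower, Ccr2 at 1.24), though not without doublet removal unless the looser naming rule was used. The cytotoxic effector list was mixed, with 4 of 24 higher, 7 lower and a median of -0.076 (Gzmc at 0.91, Prf1 at -1.19).

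The other lists did not stand apart in this comparison, with medians of -0.074 for inhibitory receptor genes (2 of 19 higher, 3 lower), -0.088 for regulatory T cell genes (4 of 22 higher, 6 lower), -0.12 for helper cytokines (2 of 8 higher, 3 lower), -0.15 for apoptosis regulators and -0.00026 for respiratory chain genes (25 of 25 between). Of these, regulatory T cell genes stood apart as lower in 4 alternative settings, apoptosis regulators in 3 and helper cytokines in 1, the last and 1 of the 3 with the main cluster of homo unnamed. Clusters 2, 3, 4 and 5 held 68.8% of the CD8-like cells of mix and clusters 1, 6 and 12 held 8.48%. Clusters 5 and 7, with Cd4 in 8.13% and 8.36% of cells, held 12.6% and 11.2% in mix, against 2.06% and 3.27% in homo. The Cd4 ratio of homo over mix can therefore reflect the makeup of the class too. The naive, memory and stem-like list no longer stood apart with the UMI gate (-0.087), where the Tcf7 ratio was 0.099, or without doublet removal (-0.12), though it did there with the looser naming rule.

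**Figure D3:**
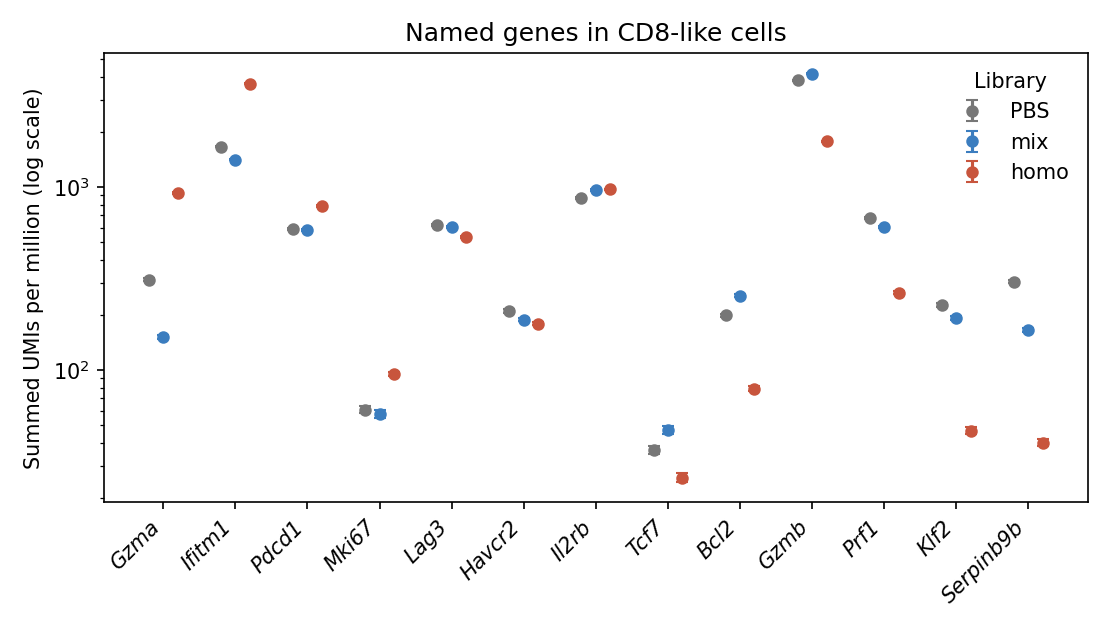
CPM in CD8-like cells of the 3 libraries for named genes, on a log axis, with exact 95% intervals for counting error. Gzma lies at 926 CPM in homo, 311 in PBS and 152 in mix, and Gzmb at 1771 in homo and 3825 in PBS.

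Shares of CD8-like cells with a UMI of a gene were compared after thinning to 2000 UMIs. Pdcd1 was found in 69.6% of cells of homo (68.4 to 70.8), against 56.8% in PBS and 56.9% in mix. Gzmb was found in 65.1% of cells of homo (63.8 to 66.3), 81.9% in PBS and 78.5% in mix. Havcr2 was found in 26.7% of cells in PBS, 24.6% in mix and 25.5% in homo. Lag3 was found in 56.2% in PBS, 57.0% in mix and 60.6% in homo, and no order is read from it because its CPM was lower in homo. Tcf7 was found in 6.33% in PBS, 8.45% in mix and 5.14% in homo.

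As a background, the same shares were taken in 110 dendritic-like cells, with a median of 5393.5 UMIs, and 105 macrophage-like cells, with a median of 6866. Both were pooled over the 3 libraries, and 66 of the macrophage-like cells came from PBS, 31 from mix and 8 from homo. CD8-like cells had medians of 5006 UMIs in PBS, 5460 in mix and 7006 in homo. In dendritic-like cells Pdcd1 was found in 15.2%, Havcr2 in 3.81%, Lag3 in 31.4%, Tcf7 in 8.57% and Gzmb in 16.2%. In macrophage-like cells the shares were 32.0%, 24.7%, 37.1%, 8.25% and 64.9% in the same order. Both were printed because the choice between them was made after the values were seen, and because macrophages express Havcr2 and plasmacytoid dendritic cells Lag3. CD3 genes were found in 81.0% of the macrophage-like cluster and in 19.4% and 55.3% of the dendritic-like clusters, so these cells hold T cell transcripts and are no clean background. The Tcf7 shares lay near the background and are not read as expression, and the Havcr2 shares and the Gzmb share of homo lay near those of macrophage-like cells. Few of the macrophage-like cells came from homo, so whether Gzmb in homo lay near the background of its own library cannot be told. Thinning left out 403 CD8-like cells in PBS, 313 in mix and 421 in homo, 5 dendritic-like cells and 8 macrophage-like cells. Without thinning, Pdcd1 was found in 73.9%, 76.0% and 88.1% of cells of PBS, mix and homo, Havcr2 in 45.4%, 45.5% and 54.4%, Lag3 in 72.2%, 75.5% and 84.1%, Tcf7 in 10.0%, 13.2% and 8.66%, and Gzmb in 87.0%, 83.9% and 77.0%.

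Regulatory-like cells numbered 1350 in PBS, 1298 in mix and 190 in homo, with 5191724, 5197390 and 791182 UMIs. In homo over PBS, interferon-stimulated genes were lower, among them the interferon-induced transcription factor Irf7 with a log2 ratio of -1.32 (-1.49 to -1.16) and the ubiquitin-like Isg15 at -1.19. Gzmb was lower at -1.21 (2784 against 6460 CPM), as were Penk, the enkephalin precursor, at -1.88, Gzma at -2.79 and Ifng at -2.94. Higher were Ifitm1 at 2.28, the lactoferrin gene Ltf at 3.21 and the granzymes Gzmd at 5.07, Gzmf at 3.65 and Gzmc at 3.31. Without doublet removal these granzymes were at 0.59, -1.10 and 0.028. Cd8a was at 0.72 in the same cells, and Cd8b1 stood at 196 CPM in homo against 99.6 in PBS and 79.1 in mix. Among 3571 genes compared, 41 were at least 2-fold higher in homo and 19 at least 2-fold lower. The total of 60 was 126 with the UMI gate, nearly evenly split, and 108 in thinned cells.

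Of the genes named in advance, Foxp3 was at -0.27 in regulatory-like cells of homo over PBS, Il2ra (CD25) at -0.54, Il2rb at -0.26, Il2rg at 0.043, Lag3 at -0.21 (0.0060 without doublet removal), Pdcd1 at 0.23, Havcr2 at -0.52, Tcf7 at 1.21, Mki67 at 0.74 and Cd4 at -0.076. Of 22 regulatory T cell genes, 3 were higher, 4 were lower and 15 lay between, with Ctla4 at -0.74 and Tnfrsf4 at -0.66, and the median of -0.19 lay at percentile 1.32. It no longer stood apart without doublet removal (-0.12), with the UMI gate (-0.14) or in thinned cells (-0.13). Of 27 IL-2 receptor and STAT5 target genes, 4 were higher and 6 lower, with Il18r1 at 1.62 and Cish at -0.92, and the median of -0.26 lay at percentile 0.020. Of 30 proliferation genes, 3 were higher and 3 lower, with Ccna2 at 0.85 and Mcm2 at -1.61, and the median of 0.036 did not stand apart. It stood apart as lower without doublet removal (-1.44), with the stricter filter (-0.31), at resolution 2.0 (-0.73), with centred components (-0.38) and with the UMI gate (-0.19).

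Interferon-stimulated genes had a median of -0.56 in homo over PBS, with 12 of 27 lower and 0 higher, and glycolysis genes -0.54, with 3 of 16 lower (Eno1 at -1.0), both below all random lists. Cytotoxic effector genes had a median of -0.18, with 7 of 22 higher and 6 lower, which turned to 0.16 with centred components and 0.055 with the UMI gate, and immediate early and heat shock genes -0.18, with 3 of 23 lower (Hspa1a at -1.56), both under the 2.5th percentile, where the stress list no longer lay in 7 alternative settings. Above the upper percentile limit lay naive, memory and stem-like genes at 0.22, with 5 of 18 higher and 4 lower (Slamf6 at 1.41, Klf2 at -0.77) though not in 4 alternative settings, and migration and residency genes at 0.25, with 4 of 19 higher (Cxcr4 at 1.16). Inhibitory receptor genes (-0.052, 3 of 18 higher and 3 lower), helper cytokines (-0.23, 1 of 7 higher and 2 lower), T cell receptor-induced genes (0.026, 2 of 17 higher and 4 lower), respiratory chain genes (-0.064, 25 of 25 between) and apoptosis regulators (0.082, 2 of 15 higher) did not stand apart. These values rest on 190 cells of homo and on their cluster: without doublet removal Mki67 was at -1.15, with the UMI gate Gzma was at 1.63, and at resolution 2.0 Tcf7 was at -0.16 and Mki67 at -0.72. Mki67 was also below 0 with centred components (-0.040) and the mean of per-cell CPM (-0.056), and helper cytokines stood apart as lower with the UMI gate.

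In regulatory-like cells of mix over PBS, cytotoxic genes were lower, with Gzma at -3.40 (-3.77 to -3.05), Ifng at -1.62, the chemokine Ccl4 at -1.03 and Prf1 at -1.14, and Ifitm1 was at -1.39. Higher were Erh at 0.85, Ywhaq at 0.79, Fah at 0.75, Filip1l at 0.75 and the interferon-induced Ifit3b at 0.68. Of 3404 genes compared, 0 were at least 2-fold higher and 5 at least 2-fold lower. The total was 2 without doublet removal and 8 in thinned cells. Foxp3 was at 0.0030, Il2ra at 0.12, Il2rb at -0.070, Il2rg at 0.014, Lag3 at -0.033, Pdcd1 at -0.025, Havcr2 at -0.12, Tcf7 at -0.18, Gzmb at -0.060, Mki67 at -0.24, Cd8a at -0.14 and Cd4 at 0.063. Medians below all random lists were -0.34 for cytotoxic effector genes (2 of 22 higher, 8 lower), -0.37 for proliferation genes (9 of 30 lower, Ube2c at -0.63) and -0.18 for glycolysis genes (2 of 16 lower, Hk2 at -1.03), and interferon-stimulated genes lay above all of them at 0.22 (2 of 27 higher, Ifit3 at 0.58). With the UMI gate Gzma was at 0.80 and Ifng at 0.38, and in thinned cells Mki67 was at 0.093.

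Among the other lists in regulatory-like cells of mix over PBS, regulatory T cell genes had a median of 0.022 with 22 of 22 between (Itgb8 at 0.53), IL-2 receptor and STAT5 target genes 0.028 with 1 of 27 higher (Il18rap at 0.61), naive, memory and stem-like genes 0.049, inhibitory receptor genes -0.025, migration and residency genes 0.071, T cell receptor-induced genes -0.042 and immediate early and heat shock genes 0.040. None of these 7 stood apart in the main setting. Migration genes did as higher in 5 alternative settings and the stress list in 3. Helper cytokines at -0.19 (Tbx21 at -0.26) and respiratory chain genes at -0.056 lay below the 2.5th percentile, and apoptosis regulators at 0.12 (Bcl2a1d at 0.47) above the upper limit. The helper list no longer stood apart in 9 alternative settings and the apoptosis list in 2.

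In regulatory-like cells of homo over mix, Irf7 was at -1.51, Isg15 at -1.43, Gapdh at -1.40, Gzmb at -1.15 and Hspa1a at -2.08, and Ifitm1 was at 3.68 (3.42 to 3.94), Gzmc at 3.70, Gzmd at 3.99, Ltf at 3.38 and Gzmf at 2.92. Without doublet removal Gzmc was at 0.14, Gzmd at 3.04 and Gzmf at -0.35. Of 3579 genes compared, 38 were at least 2-fold higher in homo and 32 at least 2-fold lower. The total of 70 was 132 with the UMI gate, with more lower than higher, and 123 in thinned cells. Foxp3 was at -0.27, Il2ra at -0.66, Il2rb at -0.19, Il2rg at 0.029, Lag3 at -0.18 (0.030 in thinned cells), Pdcd1 at 0.26, Havcr2 at -0.41, Tcf7 at 1.39, Ifng at -1.32 (0.33 with centred components), Mki67 at 0.98, Cd8a at 0.86 and Cd4 at -0.14. Regulatory T cell genes had a median of -0.29 (3 of 22 higher, 5 lower, Tnfrsf18 at -0.63), IL-2 receptor and STAT5 target genes -0.19 (3 of 27 higher, 8 lower, Ccnd2 at -0.85), interferon-stimulated genes -0.73 (18 of 27 lower), glycolysis genes -0.27 (2 of 16 higher, 3 lower) and immediate early and heat shock genes -0.24 (3 of 23 lower), all under the 2.5th percentile. Over the upper limit lay cytotoxic effector genes at 0.60 (11 of 21 higher, 3 lower, Klrd1 at 1.83) and proliferation genes at 0.36 (10 of 29 higher, 1 lower, Nusap1 at 1.53).

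The remaining lists, namely inhibitory receptor genes (0.12), naive, memory and stem-like genes (0.12), helper cytokines (-0.049), migration and residency genes (0.15), T cell receptor-induced genes (-0.042), respiratory chain genes (0.018) and apoptosis regulators (-0.050), did not stand apart in homo over mix. Migration genes did as higher in 6 alternative settings, stem-like genes as higher and T cell receptor-induced genes as lower with the UMI gate, and helper cytokines as lower in thinned cells. Without doublet removal the proliferation median was -1.11, Mki67 was at -0.99 and Cd8a at -0.097. At resolution 2.0 the proliferation median was -0.40, Tcf7 was at -0.43 and Mki67 at -0.44, and with the mean of per-cell CPM Mki67 was at -0.0019. The proliferation list did not stand apart with the stricter filter, centred components, the mean of per-cell CPM or thinned cells, the regulatory T cell list without doublet removal or in thinned cells, the IL-2 list in thinned cells, and the cytotoxic list without doublet removal.

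Over all T-like cells, taken because no CD4 conventional-like cluster was found, ratios take in the makeup of each library as well as expression. Lower in homo over PBS were Penk at -3.09, Serpinb9b at -2.85, the invariant chain Cd74 at -2.25, the transcription factor Maf at -2.19 and Tnfrsf4 at -2.00. Higher were Gzma at 1.98, Mt2 at 1.34, Ifitm1 at 1.30, Zc3h7a at 1.16 and Ifitm2 at 1.09. In mix over PBS, Fah was at 0.90, Zc3h7a at 0.84, Filip1l at 0.84, Erh at 0.82 and Ywhaq at 0.71, and Gzma was at -1.0, Gzmd at -0.93, Serpinb9b at -0.87, Nrn1 at -0.79 and Gzmk at -0.78. In homo over mix, Gzma was at 2.98, Ifitm1 at 1.55, Mt2 at 1.51, Nrgn at 1.46 and Cd7 at 1.41, and Cd74 was at -2.32, Maf at -2.21, Foxp3 at -2.01, Hspa1b at -2.01 and Serpinb9b at -1.98. At least 2-fold apart were 78 of 3097 genes for homo against PBS, 7 of 3041 for mix against PBS and 88 of 3083 for homo against mix.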

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

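The tests of treatment and of handling of the digest were chosen only after their results were seen, and the setting without cluster 6 was chosen after the data were seen. The other tests below were written before their results were known.

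Unnamed clusters entered the comparison of all T-like cells but not those of CD8-like or regulatory-like cells, and in 5 of them the interval of the share of T-like cells in a treated library lay wholly above that in PBS. In homo, cluster 11 held 3.62% against 2.79% in PBS, cluster 14 held 2.99% against 1.92%, cluster 15 held 2.61% against 0.275%, and cluster 16 held 1.13% against 0.418%. In mix, cluster 18 held 0.759% against 0.0440% in PBS. With 1 library per group, a cluster held mostly by 1 library can be that library and not a cell type. Clusters 11 and 14 were not of this kind, with 254, 213 and 264 cells and 175, 142 and 218 cells in PBS, mix and homo. Clusters 16 and 18 had low median UMIs, 1623.5 and 1442.5, so their barcodes may be of low quality, which was not tested.

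The median of the naive, memory and stem-like genes in homo over PBS had opposite signs in both classes, -0.31 in CD8-like cells and 0.22 in regulatory-like cells. The difference between the classes was not tested. The CD8-like median no longer stood apart in 5 alternative settings, among them no doublet removal, where it was -0.0074 with the main cluster of homo unnamed and -0.18 with the looser naming rule, and the regulatory-like median no longer stood apart in 4, so the contrast depends on the processing.

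The lower share of regulatory-like cells in homo was weighed against 2 technical explanations. Loss of small regulatory cells in the cell and doublet filters used here was excluded as its whole cause, since without them the share of the regulatory UMI gate in PBS was 5.50-fold that in homo (8.52% against 1.55%); loss at the earlier cell calling was not tested. Regulatory cells held in barcodes with CD8 genes were excluded as the whole cause too, since the share of CD3-positive barcodes with a Foxp3 UMI in PBS was still 2.39-fold that in homo (13.1% against 5.49%), though this fold is smaller. The treatment cannot be told apart from differences between animals, digests or sorts, because there was 1 library per group.

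Cells of cluster 15 held CD8 and regulatory genes together and numbered 190 in homo, 25 in PBS and 37 in mix. Random pairing of cells at loading was weighed on all barcodes with CD8 and Foxp3 UMIs, in cluster 15 or not. These numbered 318 in homo against 14.5 expected and 467 in PBS against 109 expected. The ratio of observed to expected in homo was 5.10-fold that in PBS, where random pairing predicted like ratios. This count also takes in stray Foxp3 UMIs in CD8 cells, which need not scale with the number of regulatory cells. Such UMIs raise the ratio most where few pairs are expected, so random pairing in cluster 15 cannot be excluded by this ratio. Cluster 15 alone, however, held 190 cells in homo, and over the 3 libraries 76.2% of its cells had a Foxp3 UMI. Random pairing at the assumed doublet rate of 6.82% gave 14.5 such barcodes in the whole homo library. These values argue against random pairing as the source of most cluster 15 cells of homo. A droplet with 2 cells cannot be excluded by T cell receptor genes. Of cluster 15 cells of homo, 71.1% (64.0 to 77.4) held 2 or more Trbv genes. This was 1.57-fold the 45.3% (42.1 to 48.5) of CD8-like cells matched on UMIs, between the bounds set for either answer. Barcodes removed as doublets in homo held them in 63.1%, so even these missed the bound of 2-fold the matched share set for doublets. Cluster 15 cells held them in 32.0% in PBS and 45.9% in mix. In homo the median of cluster 15 cells was 13383.5 UMIs, against 7006 in all CD8-like cells. Random pairing for some of the cells, and cells that stuck together before loading, may remain as causes. A biological state with both programmes was not tested apart from them.

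Immediate early and heat shock genes were lower in CD8-like cells of homo over PBS. Handling of the whole digest with an equal effect on both classes was not seen. The list's median in regulatory-like cells of the same libraries lay nearer 0 by 0.39 (interval for counting error 0.29 to 0.53). There 23 of 23 members lay nearer to or above the PBS level. The median was below 0 in regulatory-like cells too, at -0.18, and handling to which the classes respond unequally was not tested. Low-UMI cells of cluster 6 were excluded, since without them the median kept 1.11 of its size. Treatment and a difference in handling that acted on CD8-like cells more, or on them alone, stay open.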

How the results depend on the processing

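The looser naming rule without doublet removal, CD8-like cells without cluster 6 and regulatory-like cells with cluster 15 were settings chosen only after the data were seen. No paired analysis was possible because each group had 1 library and no value came from a test. Over the results that answer a comparison, 371 values under alternatives were counted as unchanged, keeping their side of the limit. Another 105 moved by more than their counting interval, or by over 1.5-fold for a count. Of the rest, 13 came to stand apart, 21 no longer stood apart and 3 were counted as turned in sign. For single genes and the other lists, these numbers were 2315, 577, 35, 45 and 34. A list that came to stand apart was counted only as such, even where its median changed sign. The proliferation median in regulatory-like cells of homo over PBS did so, from 0.036 to -1.44 without doublet removal. More signs therefore turned than were counted, and the unchanged values may hold changes of sign too. The cause of a change was not tested unless stated. In every setting run the regulatory-like share was lower in homo than in PBS, with folds from 2.90 to 6.13. By this count, median-of-ratios scaling and scaling without mitochondrial, ribosomal and T cell receptor genes turned no result named here. The regulatory-like values of homo rest on the fewest cells, 190, and on 791182 summed UMIs.

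Without doublet removal, CD8-like shares were 73.4% in PBS, 70.2% in mix and 39.8% in homo, and regulatory-like shares 13.5%, 16.01% and 2.25%. The low share in homo follows from the naming rule, since Cd160, a marker of another class, was among the leading genes of its main cluster. With names lost only at 2 leading markers the CD8-like shares were 74.8%, 71.8% and 84.2%. The stem-like list in CD8-like cells had medians of -0.0074 for homo over PBS, 0.070 for mix over PBS (standing apart as higher) and -0.12 for homo over mix, and with the looser rule -0.18 and 0.077 for the comparisons with PBS. Tcf7 in CD8-like cells was at 0.34 for homo over PBS, and at -0.16 with the looser rule. In regulatory-like cells, under either naming rule, the proliferation median was -1.44 for homo over PBS and -1.11 for homo over mix, and the regulatory T cell list -0.12 and -0.13. There Gzmf was at -1.10 and -0.35, Mki67 at -1.15 and -0.99, Lag3 at 0.0060 for homo over PBS and Cd8a at -0.097 for homo over mix. Genes at least 2-fold apart for mix against PBS numbered 2.

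With the stricter cell filter, CD8-like shares were 79.9% in PBS, 77.5% in mix and 87.1% in homo, and regulatory-like shares 13.2%, 15.5% and 2.15%. The stem-like median in CD8-like cells was -0.14 for homo over PBS. The proliferation median in regulatory-like cells was -0.31 for homo over PBS and 0.078 for homo over mix.

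At resolution 0.5, CD8-like shares were 79.7%, 76.2% and 87.4% in PBS, mix and homo. Tcf7 in CD8-like cells was at 0.15 for homo over PBS, and the IL-2 and STAT5 list at 0.039 for mix over PBS. At resolution 2.0, CD8-like shares were 70.9%, 66.5% and 74.7%, and CD4 conventional-like shares 1.65%, 1.90% and 1.43%. In CD8-like cells the inhibitory receptor median was -0.19 for homo over PBS and the stem-like median -0.078 for mix over PBS, both standing apart as lower; in the latter comparison Tcf7 was at -0.050 and Cd4 at -0.43. In regulatory-like cells the proliferation median was -0.73 for homo over PBS and -0.40 for homo over mix, Mki67 was at -0.72 and -0.44, and Tcf7 at -0.16 and -0.43.

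With components centred per library, CD8-like shares were 73.9%, 71.3% and 77.9% in PBS, mix and homo, and CD4 conventional-like shares 0.253%, 0.173% and 0.0549%. Foxp3 in CD8-like cells was at -0.019 for homo over PBS. In regulatory-like cells of homo over PBS the cytotoxic median was 0.16, the proliferation median -0.38 and Mki67 at -0.040, and for homo over mix the proliferation median was 0.0088 and Ifng at 0.33.

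With the UMI gate per cell, CD8-like shares were 78.0%, 74.5% and 90.1% in PBS, mix and homo, regulatory-like shares 9.23%, 10.8% and 1.71%, and CD4 conventional-like shares 3.47%, 4.12% and 0.967%. In CD8-like cells the stem-like median was -0.17 for homo over PBS and -0.087 for homo over mix, and Tcf7 at 0.24 and 0.099. In regulatory-like cells 126 genes were at least 2-fold apart for homo against PBS and 132 for homo against mix. For homo over PBS there the cytotoxic median was 0.055, the proliferation median -0.19, the regulatory T cell median -0.14 and Gzma at 1.63; for mix over PBS Gzma was at 0.80 and Ifng at 0.38. With cluster 15 added, the regulatory-like share of homo was 5.21%.

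Counts of genes at least 2-fold apart depend on the CPM minimum by construction. With a CPM of at least 10 they were 179, 46 and 175 in CD8-like cells for homo against PBS, mix against PBS and homo against mix, and 464, 28 and 439 in regulatory-like cells. With a CPM of at least 100 they were 43 and 42 in CD8-like cells and 31 and 40 in regulatory-like cells for homo against PBS and homo against mix. With at least 100 UMIs per list member, the stem-like median in CD8-like cells was -0.18 for homo over PBS.

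With the mean of per-cell CPM, the stem-like and proliferation medians in CD8-like cells were 0.14 and -0.043 for mix over PBS. In regulatory-like cells Mki67 was at -0.056 for homo over PBS and -0.0019 for homo over mix, where the proliferation median was 0.024. With cells thinned to 2000 UMIs, the stem-like and proliferation medians in CD8-like cells were 0.13 and -0.047 for mix over PBS. In regulatory-like cells 108, 8 and 123 genes were at least 2-fold apart for homo against PBS, mix against PBS and homo against mix. There the regulatory T cell median was -0.13 for homo over PBS and -0.16 for homo over mix, and Mki67 was at 0.093 for mix over PBS. For homo over mix the proliferation median was 0.028, the IL-2 and STAT5 median -0.19 and Lag3 at 0.030.

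Shares of CD8-like cells with a UMI scale with depth and with the minimum by construction. Not thinned, in PBS, mix and homo, they were 73.9%, 76.0% and 88.1% for Pdcd1, 45.4%, 45.5% and 54.4% for Havcr2, 72.2%, 75.5% and 84.1% for Lag3, 10.0%, 13.2% and 8.66% for Tcf7, and 87.0%, 83.9% and 77.0% for Gzmb. Thinned to 1000 UMIs, they were 38.4%, 38.5% and 49.1% for Pdcd1, 15.4%, 14.3% and 14.7% for Havcr2, 37.5%, 39.2% and 38.5% for Lag3, 4.53%, 6.0% and 2.87% for Tcf7, and 71.9%, 70.4% and 53.2% for Gzmb. With at least 2 UMIs in cells thinned to 2000, they were 32.0%, 30.9% and 41.7% for Pdcd1, 8.78%, 6.87% and 6.16% for Havcr2, 31.1%, 30.5% and 30.4% for Lag3, 2.21%, 3.35% and 1.5% for Tcf7, and 71.4%, 69.4% and 49.6% for Gzmb.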

Other observations

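No test was run for this part, and the genes in it were grouped only after their values were seen.

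A small set of genes was higher in mix than in PBS by like amounts in both classes compared. Fah was at 0.91 in CD8-like and 0.75 in regulatory-like cells, Filip1l at 0.83 and 0.75, Erh at 0.80 and 0.85, Ywhaq at 0.69 and 0.79, and Gapdh at 0.55 and 0.50.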
